A study of Mus musculus with 10 samples.

How the data were processed

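RNA-seq libraries from E14 mouse embryonic stem cells were analysed, 4 from wild-type cells and 6 from cells with the ANKRD11 Y347A mutation. Per the labels' protocols, mRNA was captured on beads in repeated rounds and libraries were made with a VAHTS Universal kit for Illumina sequencing. The deposited table holds a TPM value per gene and library, made by the authors; per the submitters' processing notes the tools were Trim Galore, STAR, RSEM and DESeq2, with the genome build mm10, and their versions, settings, strand mode and annotation release are not given in the sources used here. The table lists 55401 genes to 2 decimals. Every library sums to 1000000 TPM within rounding, so depth and counting error are unknown. TPM divides by transcript length and by the library's total, so a rise of abundant transcripts lowers all others. All 10 columns were matched to samples by their names, and 0 per-sample columns were left out.

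Genes were placed by Ensembl identifier in GENCODE M21 on GRCm38, the assembly that mm10 denotes, and 55141 identifiers matched; gene positions, types, transcript GC content and the codon of residue 347 come from there. The labels nest a replicate number in numbered sets (wild-type sets 1 and 2, mutant sets 1, 2 and 3) without saying what a set is. The main test, fixed with its alternatives and gene lists before the data were examined, therefore used set means. Values were taken as log2(TPM + 1), genes with a mean of at least 1 TPM over the 10 libraries were kept (12797 genes), the 2 libraries of each set were averaged, and 2 wild-type were compared with 3 mutant sets in limma 3.58.1 (R 4.3.3; eBayes with a mean-variance trend, 3 residual and 4.01 prior degrees of freedom, two-sided). Adjusted p are Benjamini-Hochberg values over all tested genes and the threshold was 0.05. DESeq2 was not run here, since TPM are not counts.

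Named genes were Ankrd11, the 12 most raised and 12 most lowered genes by log2 fold change among called genes whose 6 mutant libraries all lay on one side of the 4 wild-type libraries (predicted genes passed over), and per gene list up to 4 called members by size of change, or the 2 smallest p where none was called. This gave 104 genes. The 29 lists covered naive, core, formative and primed pluripotency, 2-cell-like cells, primitive endoderm, trophoblast, primitive streak and mesoderm, neural, craniofacial and skeletal genes, cohesin, the HDAC3-NCoR complex, neighbours of Ankrd11, protocadherins, Hox, imprinted, germline and Y-linked genes, p53, stress, cholesterol, hypoxia and glycolysis, Wnt, FGF-ERK and TGF-beta or BMP targets, feeder markers, histones, and mitochondrial and ribosomal transcripts. Lists with at least 5 tested members (26) were tested with limma camera on the same set means with a preset inter-gene correlation of 0.01. The p were Benjamini-Hochberg adjusted over the 26 lists. The lists were tested again with an estimated correlation and with the self-contained test fry. With an estimated correlation camera rests on the 3 residual degrees of freedom, so few sets make small p hard to reach. The trophoblast list's estimated correlation, -0.033, lay below the preset one, yet its unadjusted camera p rose from 0.049 to 0.131. A call lost in this way therefore does not show that a list's genes vary together.

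Tested on simulated set means of 12797 genes for the comparison of mutant with wild-type sets, the fit called 62% of 100 genes changed by 1 and 11% of 100 genes changed by 0.5 on the log2 scale, with 2 false calls, and called 0 of 25 unchanged lists. In that simulation many changes of moderate size were therefore missed. Its noise was drawn separately for each gene, so the list result does not cover lists whose genes vary together. The size of the noise was shuffled between genes, which removes the tie of spread to level that the variance trend uses. Changes were placed only in genes above a minimum wild-type level, so the shares do not cover low genes. It also changed far fewer genes than were called in the data, so the shares called need not hold there. Alternatives were a pseudocount of 0.1, no filter or a mean TPM of at least 5, median-of-ratios and quantile scaling, all 10 libraries with or without the set as a random block, single libraries per set, set and replicate numbers as a block, robust and trend-free variance moderation, a log2 fold change of at least 1, and leaving out each set and each library. A correction of GC content per library (lowess, span 0.3) was added after seeing the data. Figures were drawn with matplotlib 3.10.9.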

Results

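Poly(A) RNA of E14 cells, a mouse embryonic stem cell line derived from a male blastocyst, was sequenced in 10 libraries. Wild-type cells gave 4 libraries, from 2 numbered sets with 2 libraries each, and cells edited with CRISPR/Cas9 to carry the ANKRD11 Y347A mutation gave 6 libraries, from 3 numbered sets with 2 libraries each. ANKRD11 is a large nuclear protein with ankyrin repeats that acts in transcriptional regulation, and the series concerns its contact with cohesin and its part in neural and facial development. The comparison asks which transcripts differ between mutant and wild-type stem cells. The labels do not say whether a set is a clone or a culture, so p-values measure the spread between these sets and libraries, which may in part be technical. Each library sums to 1000000 TPM within rounding (transcript abundances scaled to one fixed total), so sequencing depth is unknown. Between 12473 and 12812 genes reached 1 TPM in a library. Below, levels are mean TPM ± SD over set means (n = 2 wild-type sets and n = 3 mutant sets), and log2 fold changes (mutant minus wild type, ± SE) are on the log2(TPM + 1) scale, which understates changes of low genes.

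Ankrd11 itself (ENSMUSG00000035569.17, mm10 chromosome 8, 122883822 to 123042277, minus strand) was expressed alike in both genotypes. Its TPM in the wild-type libraries was 66.0 and 65.2 in set 1 and 58.0 and 60.4 in set 2, and in the mutant libraries 69.0 and 60.5 in set 1, 53.9 and 53.4 in set 2, and 61.4 and 60.7 in set 3. The log2 fold change was -0.06 ± 0.10 with a limma adjusted p of 0.686. If the mutation is numbered on the transcript Ankrd11-202 (2643 amino acids), whose residue of that number is tyrosine, its codon is TAC (chromosome 8, 122896008 to 122896010) in exon 9 of 13. In Ankrd11-201 (2664 amino acids) the residue of that number is glycine, and the numbering used is not given in the sources used here. A change of 1 amino acid need not alter the mRNA level, so this level does not check the genotype labels.

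On the log2(TPM + 1) scale, with predicted genes passed over, the transcripts of Spic and Lefty2 fell most in the mutant, while Stk33 had the lowest ratio of mean TPM among the 12 genes named (0.0410). Spic, a transcription factor of the ETS family (ENSMUSG00000004359.16, chromosome 10, 88674772 to 88685015), fell from 37.6 ± 4.44 to 3.61 ± 0.298 TPM (log2 fold change -3.08 ± 0.12, adjusted p = 4.6e-04). Lefty2, a secreted antagonist of Nodal signalling (ENSMUSG00000066652.5, chromosome 1, 180893108 to 180899103), fell from 135 ± 0.594 to 18.1 ± 5.58 TPM (-2.88 ± 0.23, adjusted p = 0.0027). Dppa3, also called Stella, a maternal factor that protects DNA methylation in the zygote and marks naive stem cells, fell from 22.1 ± 0.318 to 3.58 ± 0.348 TPM (-2.35 ± 0.11). Peg10, an imprinted gene derived from a retrotransposon, fell from 31.6 ± 8.49 to 6.03 ± 4.60 TPM (-2.38 ± 0.46). Stk33, a serine/threonine kinase, was at 6.63 ± 0.467 and 0.272 ± 0.146 TPM, and Smoc1, an extracellular modulator of BMP signalling, at 7.96 ± 1.72 and 0.492 ± 0.192 TPM. Serpina3m fell from 8.21 ± 4.83 to 0.565 ± 0.548 TPM. Pramel6 (-2.77 ± 0.21) and Pramel7 (-2.43 ± 0.20), and on the X chromosome Xlr4b (-2.72 ± 0.35), Xlr4a (-2.46 ± 0.57) and Xlr3b (-2.28 ± 0.40), completed the 12 most lowered genes, with adjusted p between 4.6e-04 and 0.031. Xlr4a (0.4, 0.8 and 4.9 TPM) and Xlr3b (1.6, 3.0 and 6.3 TPM) also differed between mutant sets 1, 2 and 3 (limma F test, adjusted p = 0.0010 and 4.2e-04). The Pramel and Xlr genes have near-identical copies, so which copy the reads came from is uncertain.

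On the same scale the largest gain was in H1f0, the replication-independent linker histone H1.0 of slowly dividing and differentiated cells (ENSMUSG00000096210.2, chromosome 15, 79028450 to 79030504), which rose from 25.8 ± 7.78 to 121 ± 15.1 TPM, 4.67-fold (2.20 ± 0.18, adjusted p = 0.0027). Phlda2, an imprinted restrainer of placental growth, rose from 1.03 ± 0.410 to 7.37 ± 2.74 TPM (2.01 ± 0.29), the largest ratio of the 12 at 7.19-fold, and Ltbp3, a binding protein of latent TGF-beta, from 2.44 ± 0.0813 to 12.9 ± 3.08 TPM (1.99 ± 0.19). Ldhb, the B subunit of lactate dehydrogenase, rose 3.26-fold from 244 ± 26.8 to 798 ± 151 TPM. Slc11a1, a divalent metal transporter best known from macrophages, and its neighbour Catip on chromosome 1 rose 3.14-fold and 3.39-fold. Sord, sorbitol dehydrogenase, rose from 11.1 ± 4.48 to 35.1 ± 0.907 TPM. Trpm1, a cation channel, rose 2.93-fold. Adssl1, a muscle adenylosuccinate synthase, Ahnak2 (1.85 ± 0.17), Igsf21 (1.64 ± 0.16) and Igfbp4 (1.55 ± 0.36), an inhibitor of insulin-like growth factors, were the rest of the 12 most raised, with adjusted p between 0.0027 and 0.031. Igfbp4 differed between mutant sets 1, 2 and 3 as well (30.8, 12.1 and 17.8 TPM; limma F test, adjusted p = 8.9e-04). By the rule that chose them, the 6 mutant libraries of all 24 genes lay on one side of the 4 wild-type libraries.

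**Figure D1:**
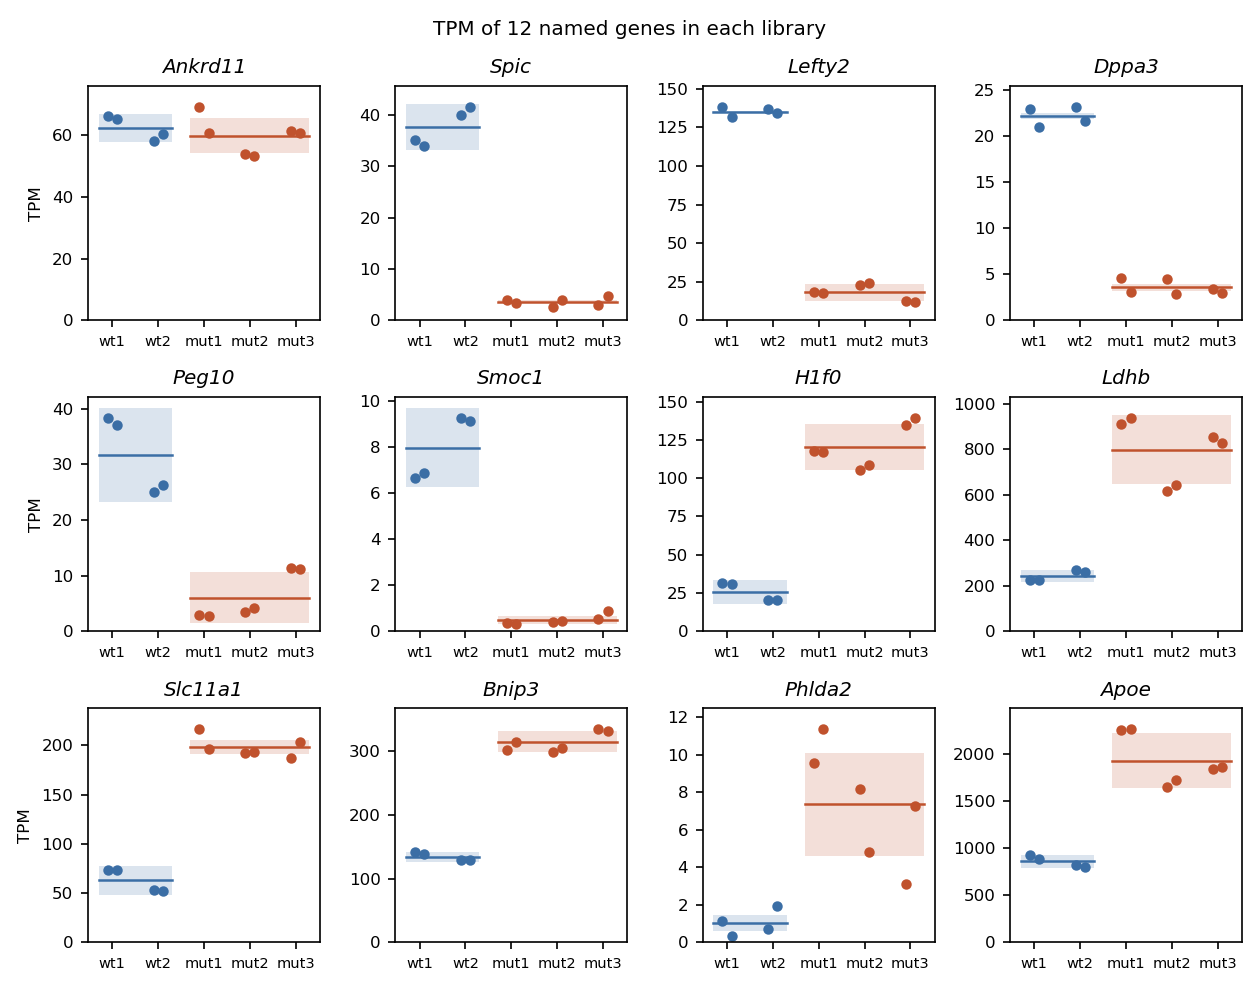
TPM (vertical axes, linear, from 0) of 12 named genes in each library of wild-type sets wt1 and wt2 (blue) and mutant sets mut1, mut2 and mut3 (orange). Points are libraries, lines are means of set means and bands are ± 1 SD (n = 2 and n = 3 sets); Ankrd11 overlaps between genotypes and the 11 other genes do not.

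Across 12797 tested genes, 2242 changed, 892 higher and 1350 lower in the mutant, at a Benjamini-Hochberg adjusted p under 0.05 (limma on set means), and 106 of the higher and 193 of the lower genes changed by at least 1 on the log2 scale. All 3 mutant sets lay on one side of both wild-type sets for 53.3% of the tested genes, where chance gives 20% on average over groupings. Genes vary together, so a single grouping of few sets can lie far from that average. The balance of directions depended on scaling, with 1095 higher and 1096 lower after median-of-ratios rescaling and 1073 higher and 1039 lower after quantile normalization. The count rested on the few sets, being 261 without wild-type set 1, 97 without wild-type set 2, 860 without mutant set 1, 2521 without mutant set 2 and 1103 without mutant set 3. Among the genes named by rule, the only ones run under each alternative, Hsd17b7 lost its call under both rescalings, Cited1, Trp53 and Fdps under quantile normalization, and Hsd17b7, Idi1, Mybl2 and Smc1b after a GC correction.

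Genes of pluripotency did not move together. Among 26 measured naive pluripotency genes, 3 rose and 6 fell (6 and 8 adjusted over the list alone), and the list as a whole was not called (limma camera, adjusted p = 0.661). Besides Dppa3, Dppa2 fell from 48.3 ± 1.27 to 27.8 ± 2.07 TPM, whereas Gbx2, a homeobox factor, rose from 12.5 ± 4.09 to 31.0 ± 2.94 TPM and Socs3, a feedback inhibitor of LIF and STAT3 signalling, from 44.4 ± 0.735 to 95.2 ± 3.59 TPM. Nanog (-0.68) and Zfp42 (-0.50), both naive markers singled out after their values were seen, also fell. Of 12 core pluripotency genes, Tdgf1 (0.30 ± 0.06) and Mybl2 (0.24 ± 0.06) rose and Lin28a (-0.77 ± 0.17) fell (3 rose and 2 fell adjusted over the list alone; list adjusted p = 0.741). Among 17 formative and primed epiblast genes, 5 fell (6 adjusted over the list alone), and none of the rest passed the test. Otx2, a homeobox factor of the epiblast and anterior brain, fell by 1.64 on the log2 scale, Lefty1 from 7.51 ± 2.40 to 2.13 ± 0.433 TPM. Dnmt3a, a de novo DNA methyltransferase, fell by 0.99 on the log2 scale. This list had an adjusted p of 0.083, and passed the threshold with no filter (0.034), at a mean TPM of at least 5 (0.045), after a GC correction (0.020), without wild-type set 1 (0.034) and without mutant set 2 (0.023), but had adjusted p = 0.568 with an estimated correlation.

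Targets of TGF-beta and BMP signalling were lower in the mutant. Of 19 measured members, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median log2 fold change of -0.43 (camera adjusted p = 0.0078). The call was lost, with adjusted p = 0.568 with an estimated correlation and adjusted p = 0.267 among genes with a mean TPM of at least 5. Beside Lefty2 and Lefty1, Id2, an inhibitor of helix-loop-helix factors, fell from 3.29 ± 0.187 to 1.23 ± 0.165 TPM. The exception was Tdgf1, the Nodal co-receptor Cripto, which rose.

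Most craniofacial and neural genes were too low to test in these undifferentiated cells. Of 53 craniofacial and neural crest genes, 15 were measured. Of these, 6 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.35 and a list adjusted p of 0.134 that reached 0.045 among genes with a mean TPM of at least 5, but adjusted p = 0.568 with an estimated correlation. Crabp1, a retinoic acid binding protein, fell from 12.8 ± 7.53 to 3.32 ± 0.854 TPM and Tfap2a, a neural crest factor, from 11.4 ± 0.912 to 4.52 ± 1.25 TPM, while Snai1, an inducer of epithelial to mesenchymal transition, rose from 1.92 ± 1.22 to 6.47 ± 0.881 TPM. Of 46 neural differentiation genes, 11 were measured. Tagln3 (-1.19 ± 0.19) and the tau gene Mapt (-0.69 ± 0.17) fell, and Sox1 (0.85 ± 0.15) and Stmn2 (0.30 ± 0.06) rose, with the same 2 and 2 adjusted over the list alone (list adjusted p = 0.568). The median of this list was 0.00 and its mean -0.08, while camera ranked it as higher. Among 9 bone and cartilage genes, Matn1 (1.07 ± 0.18) and Bmp7 (0.87 ± 0.16) rose and Col11a1 (-0.76 ± 0.18) fell (2 rose and 2 fell adjusted over the list alone; list adjusted p = 0.585).

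Markers of other early lineages went both ways. Of 11 primitive endoderm genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone; list adjusted p = 0.519). Apoe, a lipid carrier, rose from 858 ± 67.8 to 1925 ± 294 TPM and Col4a1 from 1.74 ± 0.219 to 4.18 ± 0.651 TPM, while Srgn (-1.47 ± 0.22) and the laminin Lamb1 (-0.68 ± 0.15) fell. Of 11 trophoblast genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.116). Ly6a fell from 215 ± 1.19 to 79.5 ± 19.8 TPM, Cited1 fell (-0.51 ± 0.13), and Ascl2 (0.69 ± 0.16) and the keratin Krt18 (0.53 ± 0.12) rose. Cited1 and Ascl2, whose libraries overlap between genotypes, lost the call over 10 libraries with the set as a random block (adjusted p = 0.181 and 0.078). Among 5 primitive streak and mesoderm genes, Sp5, a Wnt-responsive factor, rose from 3.11 ± 0.661 to 5.59 ± 0.155 TPM (3 rose and 1 fell adjusted over the list alone; list adjusted p = 0.134, 0.037 by fry, and adjusted p = 0.568 with an estimated correlation). Sp5 was also the only one of 12 Wnt targets to pass, over all genes or over the list alone (list adjusted p = 0.352). Of 9 fibroblast feeder markers, Cald1 fell (-0.49 ± 0.10) and the list was not called (1 rose and 2 fell adjusted over the list alone; list adjusted p = 0.669). From the 2-cell-like list only 2 genes were measured, too few for a list test, though camera called the list with no filter on mean TPM. Ddit4l, a relative of the mTOR inhibitor Ddit4, rose (0.88 ± 0.20), as it did adjusted over the list alone, but not with the set as a random block (adjusted p = 0.057).

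Of 24 measured cohesin genes and regulators, 3 rose and 3 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.519). Stag3, a meiotic cohesin subunit, rose from 33.2 ± 4.91 to 67.8 ± 9.66 TPM, Rec8, the meiotic kleisin, from 5.55 ± 1.04 to 10.5 ± 1.71 TPM, and Pttg1, the securin that restrains separase, from 89.2 ± 2.89 to 132 ± 6.87 TPM. Smc1b, another meiotic subunit, fell from 3.94 ± 0.304 to 1.79 ± 0.663 TPM. Pds5a (-0.36) and Sgo2a (-0.31) fell as well. The core subunits Rad21 (-0.20, adjusted p = 0.074), Smc1a (-0.10, adjusted p = 0.503) and Smc3 (-0.09, adjusted p = 0.573) did not pass, and these 5 genes were singled out after their values were seen. The 15-gene list of ANKRD11 relatives and the HDAC3-NCoR complex also holds genes that belong to neither, such as Ncoa1, Kat5 and Trp53. Trp53, which encodes p53, fell from 182 ± 12.1 to 129 ± 16.3 TPM. It was the only call in that list over all genes and over the list alone (list adjusted p = 0.541). Of 27 measured neighbours of Ankrd11 on chromosome 8, 4 rose and 1 fell, counts that were equal adjusted over the list alone. Cyba, a subunit of NADPH oxidase, rose from 20.2 ± 3.08 to 51.3 ± 13.6 TPM, Rnf166 (0.60 ± 0.13) and Galns (0.57 ± 0.14) rose, and Ctu2 (-0.38 ± 0.09) fell, a call lost with the set as a random block (adjusted p = 0.066). The list adjusted p was 0.086, with 0.034 under no filter, 0.039 without mutant set 2, 0.775 after a GC correction and adjusted p = 0.568 with an estimated correlation. Of 58 clustered protocadherins, whose promoter choice depends on cohesin and CTCF, 4 were measured and none of them passed (limma, smallest unadjusted p = 0.071). Pcdhga1 was at 1.16 ± 0.382 and 1.84 ± 0.333 TPM and Pcdhgc4 at 18.2 ± 3.98 and 15.0 ± 2.08 TPM. The list had too few members for a list test, though camera called it with no filter on mean TPM. Of 4 measured Hox genes, 2 rose, and the same 2 adjusted over the list alone, among them Hoxc13 (0.48 ± 0.12).

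Genes of hypoxia and glycolysis were higher in the mutant. Of 28 measured members, 16 rose and the other 12 did not pass the test (20 rose adjusted over the list alone), with a median log2 fold change of 0.34 (camera adjusted p = 3.7e-10, and adjusted p = 0.358 with an estimated correlation). Bnip3, a mitophagy receptor induced by hypoxia, rose from 135 ± 7.77 to 314 ± 16.3 TPM, Egln3, an oxygen-sensing prolyl hydroxylase, from 9.34 ± 2.10 to 23.1 ± 2.50 TPM, Ndrg1 from 22.5 ± 0.0778 to 49.5 ± 2.55 TPM, and Ddit4 from 86.7 ± 13.7 to 175 ± 17.6 TPM. The p53 targets also rose more often than they fell. Of 26 measured, 10 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.31, camera adjusted p = 2.5e-04, and adjusted p = 0.568 with an estimated correlation). Dcxr, a carbonyl reductase, rose from 15.5 ± 3.26 to 41.0 ± 8.65 TPM and Btg2, an antiproliferative factor, rose by 0.89 on the log2 scale, while Pmaip1, the apoptosis factor Noxa, fell from 17.0 ± 0.428 to 10.6 ± 1.04 TPM. Ddit4 belongs to both lists. The self-contained test fry, which does not compare a list with the other genes, called both (adjusted p = 0.017 for hypoxia and glycolysis and 0.037 for p53 targets). Of the other lists called by camera, fry also called the TGF-beta and BMP targets (adjusted p = 0.041) and the replication-dependent histones (adjusted p = 0.037), but not the rest.

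**Figure D2:**
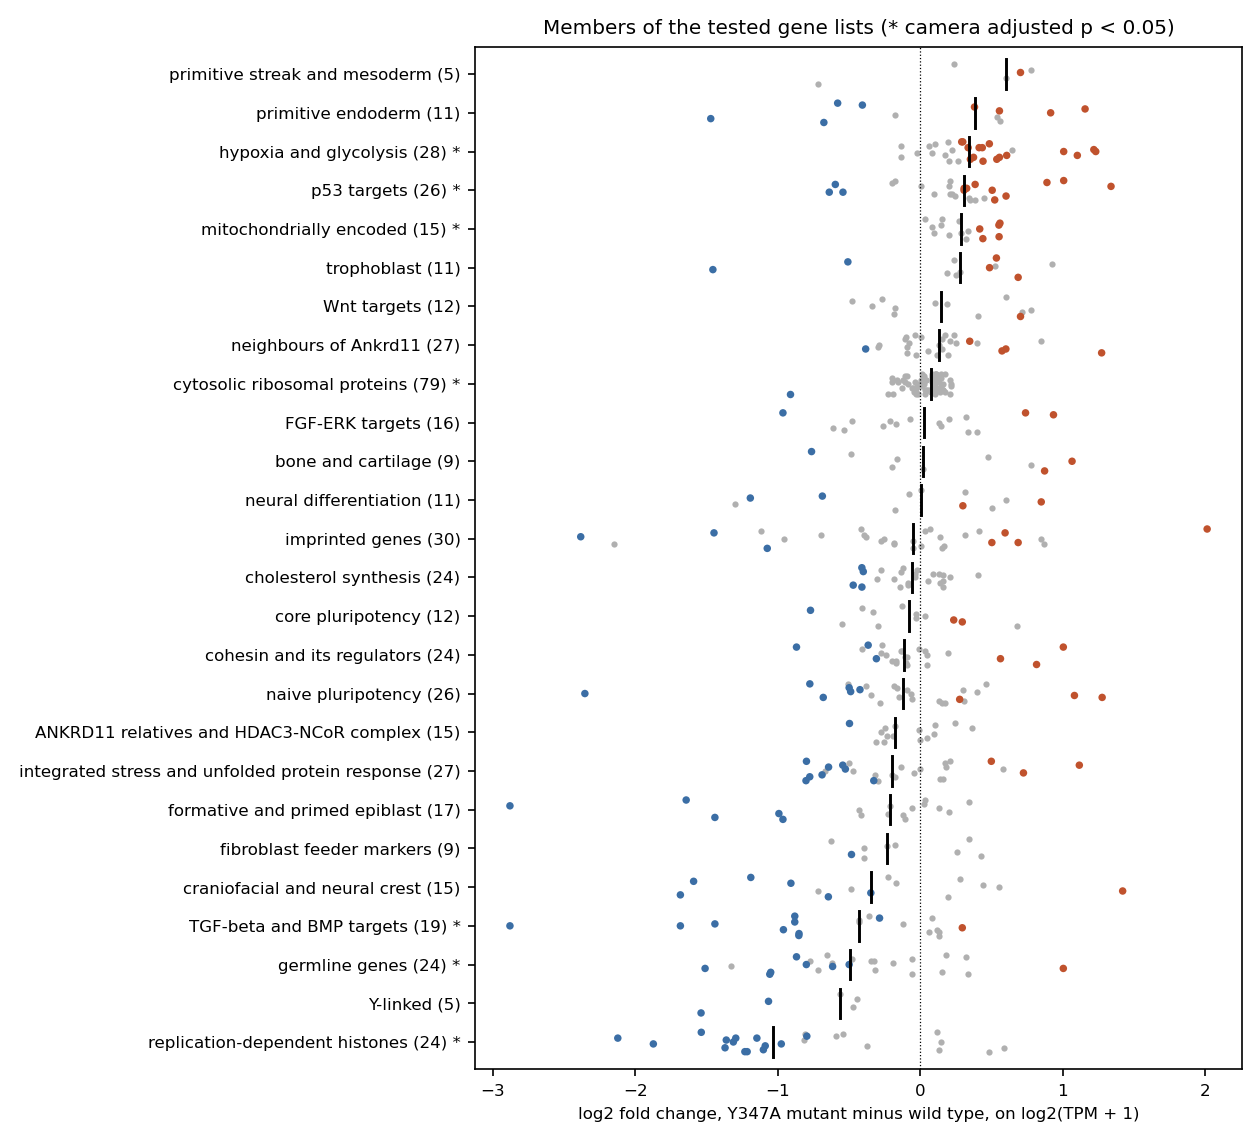
Log2 fold change (horizontal axis, mutant minus wild type) of each measured member of the gene lists with at least 5 measured members (number in brackets). Orange and blue points passed adjusted p under 0.05 as higher and lower, and grey points did not. Black bars are list medians, from -1.03 for replication-dependent histones to 0.60 for primitive streak and mesoderm. Stars mark the 7 lists called by camera with a preset correlation. None of these was called with an estimated correlation, a test that rests on only 3 residual degrees of freedom.

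Among 27 measured genes of the integrated stress and unfolded protein responses, 3 rose and 8 fell (3 and 11 adjusted over the list alone; list adjusted p = 0.131). Its adjusted p was 0.034 with no filter, 0.045 at a mean TPM of at least 5, 0.044 after a GC correction and 0.0049 without mutant set 3, but adjusted p = 0.787 with an estimated correlation. Psat1 and Phgdh, enzymes of serine synthesis, fell (-0.77 ± 0.10 for Psat1), and Mthfd2, a mitochondrial folate enzyme, fell from 94.9 ± 1.73 to 54.5 ± 9.64 TPM, whereas Ddit3, the stress factor CHOP, rose from 31.5 ± 1.23 to 71.3 ± 19.3 TPM. Of 24 cholesterol synthesis genes, 4 fell (6 fell and 1 rose adjusted over the list alone; list adjusted p = 0.585), among them Fdps (-0.41 ± 0.08), Idi1 (-0.40 ± 0.07) and Hsd17b7 (-0.47 ± 0.13, adjusted p = 0.0499). Of 16 targets of FGF and ERK signalling, Fos (0.94 ± 0.16) and Jun (0.74 ± 0.16) rose and Etv4 fell from 30.2 ± 0.378 to 15.2 ± 2.73 TPM, the same 3 adjusted over the list alone (list adjusted p = 0.708). The median of this list was 0.03 and its mean -0.01.

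Germline genes were lower as a list. Of 24 measured, 7 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.49, camera adjusted p = 0.038, and adjusted p = 0.568 with an estimated correlation). Dazl, an RNA-binding protein of germ cells, fell from 16.4 ± 4.45 to 5.03 ± 0.149 TPM, Meioc from 6.73 ± 0.647 to 2.80 ± 0.882 TPM and Tuba3a from 44.2 ± 16.2 to 20.3 ± 3.95 TPM, and Stag3 was the gene that rose. The adjusted p was 0.370 at a mean TPM of at least 5, 0.144 without wild-type set 2, 0.085 without mutant set 2, 0.084 without wild-type library 1-1, 0.052 without wild-type library 2-2, 0.073 without mutant library 2-1, 0.067 from the second libraries alone and 0.066 by fry. Of 30 imprinted genes, 4 rose and 3 fell, over all genes and over the list alone (list adjusted p = 0.962). Beside Phlda2 and Peg10, Mest fell from 23.9 ± 1.39 to 8.36 ± 2.63 TPM and Peg3 by 1.07 on the log2 scale. Imprinted levels also varied between mutant sets. Peg10 was at 2.9, 3.9 and 11.3 TPM in mutant sets 1, 2 and 3 (limma F test between these sets, adjusted p = 6.7e-05). Meg3 (152, 150 and 368 TPM) and Snrpn (27.1, 29.9 and 60.8 TPM), singled out after their values were seen, differed as well. Of 5 measured Y-linked genes, Zfy1 fell from 3.98 ± 0.827 to 0.708 ± 0.164 TPM and Uba1y from 6.30 ± 1.96 to 2.50 ± 0.823 TPM, over all genes and over the list alone (list adjusted p = 0.088, 0.0024 with no filter, 0.0049 without mutant set 3, but adjusted p = 0.681 with an estimated correlation). The list median was -0.73 in mutant set 1, -1.46 in mutant set 2 and 0.04 in mutant set 3. Y-linked genes have X-linked or autosomal relatives that can share reads.

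Replication-dependent histone transcripts were lower in the mutant. Of 24 measured genes, 14 fell and the other 10 did not pass (15 fell and 1 rose adjusted over the list alone; median -1.03, camera adjusted p = 9.9e-05, and adjusted p = 0.358 with an estimated correlation). H2bc11 fell from 7.38 ± 0.0318 to 0.970 ± 0.619 TPM and H4c2 from 6.11 ± 0.113 to 1.11 ± 1.01 TPM. H2ac12 fell from 12.4 ± 2.92 to 3.59 ± 0.958 TPM and H2bc12 from 13.2 ± 1.90 to 4.55 ± 1.55 TPM. The small wild-type SDs hide a wide spread within sets. In the libraries of wild-type set 1, H2bc11 was at 4.10 and 10.7 TPM and H4c2 at 8.14 and 4.23 TPM. The libraries of H2bc12 overlap between genotypes (7.02 TPM in wild-type library 2-2 and 7.91 TPM in mutant library 3-2). These mRNAs mostly lack a poly(A) tail and their genes are near-identical, so levels in poly(A) libraries are residual and single copies are uncertain. Mitochondrially encoded transcripts took 6.61 ± 0.437% of all TPM in wild-type and 7.84 ± 0.874% in mutant sets. The libraries of mutant set 1 (7.03 and 6.86%) overlapped those of wild-type set 1 (6.98 and 6.86%), while mutant set 2 was highest (8.71 and 8.67%). List medians in mutant sets 1, 2 and 3 were 0.15, 0.54 and 0.30. Of 15 such genes, 5 rose, over all genes and over the list alone (median 0.29, camera adjusted p = 1.8e-04, and adjusted p = 0.568 with an estimated correlation), with mt-Co3 up 1.47-fold, mt-Nd6 up 1.47-fold, mt-Nd5 up 1.36-fold and mt-Nd3 up 1.46-fold. The libraries of mt-Nd3 overlap between genotypes and its call was lost with the set as a random block (adjusted p = 0.124), and the list was not called by fry (adjusted p = 0.155). Cytosolic ribosomal proteins took 24.4 ± 0.485% and 25.3 ± 1.08% of TPM. Camera called their 79 genes as higher (median 0.08, adjusted p = 0.038, and adjusted p = 0.787 with an estimated correlation), although the single gene that passed over all genes or over the list alone, Rpl22l1, fell from 795 ± 3.21 to 422 ± 14.0 TPM. That list's direction turned under quantile normalization (adjusted p = 0.808), and its call was lost without wild-type set 1 (0.506), mutant set 1 (0.388), wild-type libraries 1-1 (0.084) or 2-1 (0.072), or mutant libraries 1-2 (0.074) or 2-1 (0.073), from the second libraries alone (0.094), after a GC correction (0.105) and by fry (0.632).

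Sets of one genotype also differed from each other. Between the 2 wild-type sets 352 genes differed, and between the 3 mutant sets 2507 genes (limma with sets as groups and the 2 libraries of a set as replicates, adjusted p under 0.05). By pairs, 1747 genes differed between mutant sets 1 and 2, 866 between 1 and 3 and 1728 between 2 and 3. Of the 2242 genes called between genotypes, 487 also differed between mutant sets and 88 between wild-type sets. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.983 to 0.986 within sets, 0.977 to 0.984 between sets of a genotype and 0.962 to 0.972 between genotypes. The imprinted gene Plagl1 was at 173 and 121 TPM in the wild-type sets and at 56.0, 4.33 and 117 TPM in mutant sets 1, 2 and 3, so no shared change could be called (adjusted p = 0.230). Eif2s3y, on the Y chromosome, was at 126 and 135 TPM in the wild-type sets and at 125, 40.8 and 135 TPM in mutant sets 1, 2 and 3, and the Y-linked Ddx3y at 34.7 and 40.4 against 22.2, 15.7 and 53.8 TPM. Plagl1, Eif2s3y and Ddx3y were singled out after their values were seen, for their differences between mutant sets.

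No autosome carried a shift of the size that a gained or lost copy would give. Median log2 fold changes per autosome lay between -0.11 (chromosome 14) and 0.03 (chromosome 17), against 0.58 for 3 copies in place of 2, and between -0.15 and 0.06 in any single mutant set. The 672 tested genes of chromosome 8, which holds Ankrd11, had a median of -0.01. The 416 tested genes of the X chromosome had a median of -0.14. The 11 tested genes of the Y chromosome had a median of -0.44, with -0.20 in mutant set 1, -0.98 in mutant set 2 and 0.31 in mutant set 3. Whether some cells of mutant set 2 lack this chromosome was not tested.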

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

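Tests chosen after the result, or values that decide it, had been seen were the GC correction of the gene count, the split of the sets for the hypoxia genes and the test of RNAs without a poly(A) tail, and the GC correction itself was chosen after seeing the data.

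In 208 groups of libraries, 4 wild-type or 6 mutant libraries for each named gene, 3 held a library far from the others. Chance gives about 1 in 20 if libraries are independent. The 2 libraries of a set are not, and a set that lies apart as a whole would be missed, so the low number does not clear the libraries. Crabp1 was at 5.43 TPM in mutant library 1-2 and at 2.32 to 3.30 TPM in the other mutant libraries. Smoc1 was at 0.880 TPM in mutant library 3-2 and at 0.340 to 0.540 TPM in the others, and Krt18 was at 6.6 TPM in mutant library 3-2 and at 5.06 to 5.43 TPM in the others.

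The count of 2242 changed genes was set against other groupings of the 5 sets. Of the 10 splits into 2 and 3 sets, 1 gave a count as large, the real one, and the highest count of the other splits was 2 genes. However, 10 splits are too few for a share under 0.05. Every other split also mixes the genotypes, so a genotype difference widens its spread and can lower its count. The other counts therefore do not show how many calls set differences alone would give. Fold changes followed transcript GC content (Spearman 0.246 across genes), with medians of -0.13 in the 25% of genes with the lowest and 0.07 in the 25% with the highest GC content. After a GC correction in each library, 1722 of the 2242 calls were kept with the same sign among 2057 calls, which argues against the GC trend as the source of most calls. The mutation and any other difference between the wild-type and mutant sets, such as clonal history, cannot be told apart in this design of 2 against 3 sets.

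The rise of hypoxia and glycolysis genes was weighed against the same trend. After the GC correction the list's median was 0.30 in place of 0.34, with a camera adjusted p of 1.4e-08, which argues against GC content as its cause. Among the 10 splits of the sets, 1 gave a list median as large in size as 0.34, the real one. The highest of the others was 0.25, again too few splits for a share under 0.05. Those others mix the genotypes too, so their medians can hold part of the genotype difference. Whether the members move together with oxygen, density or medium in each culture, whatever the genotype, stays open, since the labels describe no culture conditions per set.

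The fall of replication-dependent histone transcripts has 3 candidate explanations. A GC trend is argued against, since the median was -1.13 after the correction and -1.03 before (camera adjusted p = 2.3e-06). Less carry-over of RNA without a poly(A) tail cannot be told apart from a real fall. The 27 snRNA, snoRNA and scaRNA genes had a median of -0.47, with a bootstrap interval over genes of -0.92 to -0.15. That interval is too wide to decide, even without the spread between sets, and many of these genes are listed at 0 in some libraries. Fewer cells in S phase, when these histones are made, is in line with the lower median of 40 other S phase genes, -0.36 (20 fell and 1 rose; unadjusted camera p = 1.9e-09, p = 0.210 with an estimated correlation), and stays a hypothesis. These 40 genes were listed after the lower histones and Cdc45 had been seen, without Cdc45, and lie outside the 29 fixed lists.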

How the results depend on the processing

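The GC correction was chosen after the data were seen and all other settings before. The count of changed genes (2242; 892 higher, 1350 lower) stayed within 1.5 times under a pseudocount of 0.1, a mean TPM of at least 5, both rescalings, robust or trend-free moderation and the GC correction. It was 809 (250 higher, 559 lower) with no filter, where 26268 genes were tested; 3398 (2063 lower, 1335 higher) over 10 libraries with the set as a random block, and 5269 (2166, 3103) as independent libraries, where more samples enter; 1172 (459, 713) from the first and 975 (386, 589) from the second library of each set; and 299 (106, 193) at a log2 fold change of at least 1. The cause of the other moves was not tested. Sets with equal numbers did not deviate together (r = -0.16 and -0.09), nor did replicate numbers (over 0.1 in 2 of 10 pairs of sets), so numbers were not taken as pairs; with the set number as a replicate block 571 genes (209, 362) were called and with the replicate number as a replicate block over 10 libraries 4998 (2054, 2944). Leaving out a set or library in turn gave 97 to 2521 changed, 38 to 1063 higher and 59 to 1458 lower genes, the lowest without wild-type set 2, where 1 wild-type set is assumed to vary like the others. No call changed sign under any setting. Of 103 named genes besides Ankrd11, 101 were called, and 78 lost the call without wild-type set 2, 64 without wild-type set 1, 59 with no filter and none with a pseudocount of 0.1. Ankrd11 was called under no setting. The number of called lists (7 of 26) was 13 of 29 with no filter, 11 of the same 26 and 2 with too few members otherwise (2-cell-like genes and protocadherins), and 0 with an estimated correlation, and 5 to 9 without a set or library; lists were not run with the random block, which camera does not take. Ribosomal proteins turned direction under quantile normalization (adjusted p = 0.808). The 352 and 2507 genes that differed between wild-type and between mutant sets stayed within 1.5 times under the 3 settings tried. The lowest median of any autosome, -0.11 (chromosome 14), compares with -0.154 in mutant set 1 (chromosome 13) and -0.0607 between the wild-type sets (chromosome 18), and the highest, 0.03 (chromosome 17), with 0.0588 in mutant set 3 (chromosome 17) and 0.0754 between the wild-type sets (chromosome 14). TPM keep no depth, so genes near 1 TPM cannot be weighed by their counts.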

Other observations

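The S phase and G2/M lists were drawn up after the data had been seen, and the tests of them after the lower histones (S phase) or the lower S phase genes (its GC correction and G2/M), each before its own result; Psrc1, in the G2/M list, had been seen to rise. Of 40 S phase genes, 20 fell, 1 rose and the rest did not pass; as a list they were lower (unadjusted camera p = 1.9e-09), which was lost with p = 0.210 with an estimated correlation. Ccne1, cyclin E1, fell from 82.3 ± 4.28 to 49.9 ± 7.31 TPM, Nasp, a histone chaperone, by 0.70 on the log2 scale, Pcna, the sliding clamp, from 393 ± 1.47 to 294 ± 30.1 TPM, and Slbp, which binds the stem-loop of histone mRNAs, from 132 ± 1.02 to 102 ± 8.65 TPM. Of 40 G2/M genes, 3 rose and 4 fell, among them Psrc1, a spindle protein and p53 target, which rose from 106 ± 4.61 to 207 ± 13.4 TPM, and Cdk1, which fell from 401 ± 7.02 to 332 ± 16.5 TPM.

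Several abundant transcripts outside the lists, chosen after their values were seen, also separated the genotypes. Mt1, a metallothionein that binds zinc, rose from 717 to 1616 TPM, Neat1, the noncoding RNA of paraspeckles, from 74.3 ± 6.89 to 179 ± 22.2 TPM, and Ndufa4l2, a mitochondrial protein induced by hypoxia, from 47.4 ± 2.50 to 133 ± 24.8 TPM. Fabp5, a fatty acid binding protein, fell from 97.8 ± 11.2 to 26.9 ± 1.63 TPM, Klhl13, an X-linked ubiquitin ligase adaptor, from 69.1 ± 5.97 to 17.6 ± 4.57 TPM, and Ube2l6, an ISG15-conjugating enzyme, by 2.18 on the log2 scale.

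A candidate explanation is that the GC trend lowered the S phase genes. After the GC correction their median was -0.29 in place of -0.36 (bootstrap interval over genes -0.34 to -0.21). This argues against the trend as the source of the whole fall. A second is that fewer mutant cells were cycling at all. The 40 G2/M genes had a median of -0.0415 (bootstrap interval over genes -0.10 to 0.04), so as a group they showed no fall of the size of the S phase genes. Neither of these 2 intervals holds the spread between sets. Mki67, for one, was at 26.6, 30.7 and 35.8 TPM in mutant sets 1, 2 and 3, and at 34.9 and 30.4 TPM in the wild-type sets. Fewer cycling cells are therefore not excluded. A shorter S phase, or lower expression of replication genes in each cell, is also possible, and neither was tested.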
